A study of Mus musculus with 2 samples.

How the data were processed

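Gene expression was measured in ureters dissected from mouse embryos at embryonic day 14.5, the paired tubes that carry urine from kidney to bladder. Per the labels, the Bmp4cKO embryos carried a Tbx18 allele with cre in place of 1 copy and 2 floxed Bmp4 alleles, so that Bmp4 is removed where Tbx18 is active, and controls carried no cre. There were 2 two-colour arrays, each with 1 Bmp4cKO and 1 control RNA, and the dyes were swapped between them. On replicate 1, labelled female in both channels, the control RNA carried the red dye AlexaFluor647 and the Bmp4cKO RNA the green dye AlexaFluor555. On replicate 2, labelled male in both channels, the dyes were the other way round. Whether an RNA came from 1 embryo or a pool is not given in the sources used here. The p-values rest only on differences between these 2 arrays, and mostly on a variance shared over all genes.

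Per the file headers, the authors scanned the arrays and quantified the spots with Agilent Feature Extraction 10.7.3.1, and probe positions are those of mouse build mm9. The deposited spot and background values are intensities on a linear scale, as scanned. The deposited processed signals are intensities that the software had detrended and dye-normalized, per the file headers, and the deposited log ratio is the log10 of red over green processed signal. The authors' value table holds a score per probe, which set against the scanner values proved to be a signed fold change. Its size lay within 0.01 (log2) of the scanner's log ratio for 99.3% of the probes above background on both arrays. It carried the sign of red over green on replicate 1 and of green over red on replicate 2, and the median of both columns was 1. The sample titles read Bmp4cKO vs control, but no source used here says that this is the order of the ratio in the table.

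Each array had 44397 spots, 1377 of them controls. Median spot intensity over median local background was 14.9 in green and 7.14 in red on replicate 1, and 15.6 and 7.58 on replicate 2. Between 69.3% and 74.6% of probe spots were well above background in a channel. No probe spot was saturated. Outlier marks fell on 231 and 235 probe spots, which were left out. The number of arrays, 2, limits the precision.

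Background was corrected with normexp (offset 50) and red over green was normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots of a probe were averaged, which concerned 399 probes of 10 spots each. Of 39429 probes, 31019 were named through a RefSeq accession, symbol or synonym in a table of assembly GRCm38.p6, used for names only, and 8410 kept the array's name. A probe was kept where it was well above background in both channels labelled Bmp4cKO or both labelled control. Each gene was represented by its brightest passing probe, leaving 21971 genes. Of the named genes, 11 had more than 1 passing probe, and for 1 of them, Cdk1, a probe had the opposite sign.

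Ratios were turned so that each value is log2 of the RNA labelled Bmp4cKO over the RNA labelled control, the direction the dye labels give. The 2 arrays were fitted with lmFit and eBayes without a trend, and p-values were adjusted by Benjamini-Hochberg. With 1 residual degree of freedom per gene and 4.05 prior degrees of freedom, the shared prior carried most of each test. A second description counted genes changed at least 2-fold in the same direction on both arrays. Of 26 gene lists, 25 were tested with camera at a preset correlation of 0.01 and adjusted over lists, and the sex-linked list served as a label check. The correlation that camera can estimate rests here on the same 1 residual degree of freedom, so it is itself imprecise. With it, camera also takes its p-values from 1 degree of freedom, where hardly any list can pass. Kidney stroma genes had an estimated correlation of -0.11, below the preset 0.01, yet their unadjusted camera p went from 9.6e-04 to 0.18. A call lost in that setting therefore says little. At the preset 0.01, camera takes the members of a list as nearly uncorrelated, and its p-values rest on genes rather than on arrays. A very small p there does not measure agreement between the 2 arrays. The imprecise estimates were 0.33 for urothelial and 1 for endothelial genes. With limma's fry, the other planned list test, 0 lists passed after adjustment. The lists, the tests of genes and lists, and the alternatives were fixed before the data were examined, except for 2 alternatives, without genes of chromosomes X and Y and with the sign of the authors' value table, and the tests of explanations in the closing section, which were added later. The rule for naming genes was also fixed at the start and took Bmp4 and Tbx18, the 12 largest rises and 12 largest falls past the threshold that moved alike on both arrays, up to 4 called members of each list or else the 2 with the largest change, and the sex-linked genes. Some genes that this rule takes are not reported here. Where a gene was not well above background in either channel of a group, the fold is a bound, computed per channel after loess and Aquantile.

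The steps were tested on simulated data for this comparison, with noise drawn from the fitted prior. Of 21971 genes 200 were changed, and a list of 20 others was raised 1.5-fold. Of 66 genes changed 4-fold, 83.3% were called. Of 67 genes changed 2-fold none was called, nor was any of 67 changed 1.5-fold, although the median estimate for 2-fold was 1.89. Of 57 simulated calls, 2 were false. The real arrays had 427 called genes, so the adjustment was stricter in the simulation, and these recovered shares do not carry over. The simulated noise was independent between probes, and its only dye effect was a straight slope with signal. The share of false calls therefore does not carry over either. Alternatives covered the background correction, normalization, filter, probe choice, value source, variance model, handling of channels, thresholds, list test and each array left out. Figures were drawn with matplotlib 3.10.9.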

Results

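Ureters of Bmp4cKO and control embryos were compared on 2 arrays of opposite dye orientation, with 1 RNA of each genotype per array. The comparison asks which transcripts differ when Bmp4, a secreted signal of the bone morphogenetic protein family, is removed from the Tbx18-expressing mesenchyme. Across 21971 genes the log2 ratios of the arrays correlated at a Pearson's r of 0.48 and a Spearman's rho of 0.31, across genes that are not independent replicates.

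Bmp4, the targeted gene, was higher in the RNA labelled Bmp4cKO on both arrays, against the label. Its log2 ratio was 3.04 on replicate 1 and 3.71 on replicate 2, a mean of 3.38 ± 0.48 (SD, n = 2 arrays; limma adjusted p = 0.016). The authors' value table runs the opposite way, with signed folds of -8.16 and -13.9 for this probe in the authors' deposited table. The probe lies on chromosome 14 from 47003391 to 47003450 in mm9, and whether that stretch is within the deleted part is not given in the sources used here. If it lies outside, it checks nothing. The check rests on 1 of 2 Bmp4 probes, since the other, from 47003198 to 47003257, was not well above background in any channel. Tbx18, a transcription factor gene of ureteric mesenchyme of which the Bmp4cKO genotype has 1 intact copy, was also higher in the RNA labelled Bmp4cKO, with a mean log2 of 0.97 ± 0.17 (SD, n = 2 arrays; limma adjusted p = 0.039). Its probe lies on chromosome 9 from 87599514 to 87599573. Every direction below follows the dye labels and turns if the dye labels are exchanged.

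The sex-linked genes matched the labels on replicate 1 and not on replicate 2. On replicate 1, labelled female, Xist had processed signals of 1859 and 1536, and Ddx3y was not well above background in either channel. On replicate 2, labelled male, the RNA labelled Bmp4cKO had an Xist signal of 1464 and no Ddx3y or Eif2s3y well above background. The RNA labelled control on that array had 2720 for Ddx3y, 2741 for Eif2s3y and 4.31 for the same Xist probe, which was not well above background. A second Xist probe had 2120 in the RNA labelled Bmp4cKO and 85.2 in the RNA labelled control of that array, both well above background. On replicate 2, the Xist and Y-linked signals therefore differed between the channels together with the genotype labels. Without genes of chromosomes X and Y, an alternative chosen after seeing the data, 191 genes were higher and 221 lower.

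**Figure D1:**
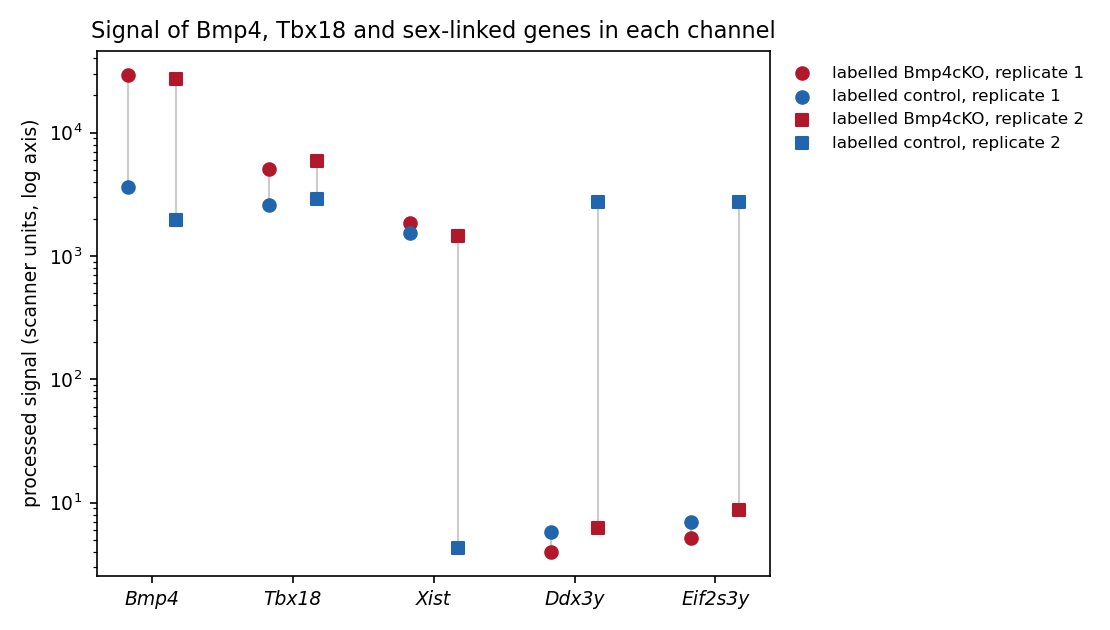
Processed signal in scanner units on a log axis for 1 probe each of Bmp4, Tbx18, Xist, Ddx3y and Eif2s3y, with red points for the RNA labelled Bmp4cKO, blue for the RNA labelled control, circles for replicate 1 and squares for replicate 2. Bmp4 and Tbx18 are higher in the RNA labelled Bmp4cKO on both arrays, while Xist and the Y-linked genes part the channels on replicate 2.

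Genes of the urothelium, the epithelium that lines the ureter, and a smooth muscle gene were among the 12 largest rises, which go in the direction of Bmp4. Upk1b, which encodes a uroplakin of the urothelial surface, had a mean log2 of 3.72 ± 0.82, Upk3a 2.48 ± 0.42 and Upk2 2.41 ± 0.76 (SD, n = 2 arrays). Myh11, the smooth muscle myosin heavy chain, had 2.48 ± 0.90. Car3 was 8.59-fold higher, and Rab27b, Sprr1a, Ldoc1, Perp, Ctse and Shisa2 had means between 2.41 and 2.79. In the opposite direction, Nts, which encodes the peptide neurotensin, fell by 3.92 ± 0.16 on the log2 scale, the furthest of the named genes. Cltrn fell by 2.44 ± 0.30 and Osr2 fell by 2.14 ± 0.05. Gdnf, the ligand of the receptor Ret, had a mean of -2.15 ± 0.17. Kcnd3, C1qtnf7, Evx1, Aldh1a3 and Dclk3 fell by 2.06 to 2.33. Evx1 was well above background in the RNA labelled Bmp4cKO on 1 array only, and was at -3.35 with the processed signals. A dimmer probe of Rab27b was at 2.08 and one of C1qtnf7 at -0.79. Aoc1 was not well above background in the RNA labelled Bmp4cKO on either array and was at least 3.81-fold lower. Mup9 and Mup19, with means of -2.34 and -2.33, belong to a family of near-identical genes whose probes may not tell members apart, and are uncertain.

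In all, 197 genes were higher and 230 lower in the RNA labelled Bmp4cKO (limma, adjusted p under 0.05), each with the same direction on both arrays, and the smallest called change was 1.74-fold. With the sign of the authors' value table the counts exchange to 230 higher and 197 lower. At least 2-fold on both arrays were 128 genes higher and 136 lower, while 41 genes were at least 2-fold in opposite directions. The calls depended on the loess step: with median centring in its place 0 genes passed, while 1761 had an unadjusted p under 0.05 and 120 higher and 148 lower genes still met the 2-fold rule. With a robust prior Upk1b, Upk2, Myh11, Actg2, Sprr1a, Aldh1a3 and Msx2 no longer passed, nor did Aldh1a1 with the processed signals, and in fits of separate channels without a replicate block or with a dye term Bmp2, Smad9, Cyp26b1, Apcdd1, Lgr5, Elavl3, Myog, Upk3b and Ptprc each failed at least 1.

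**Figure D2:**
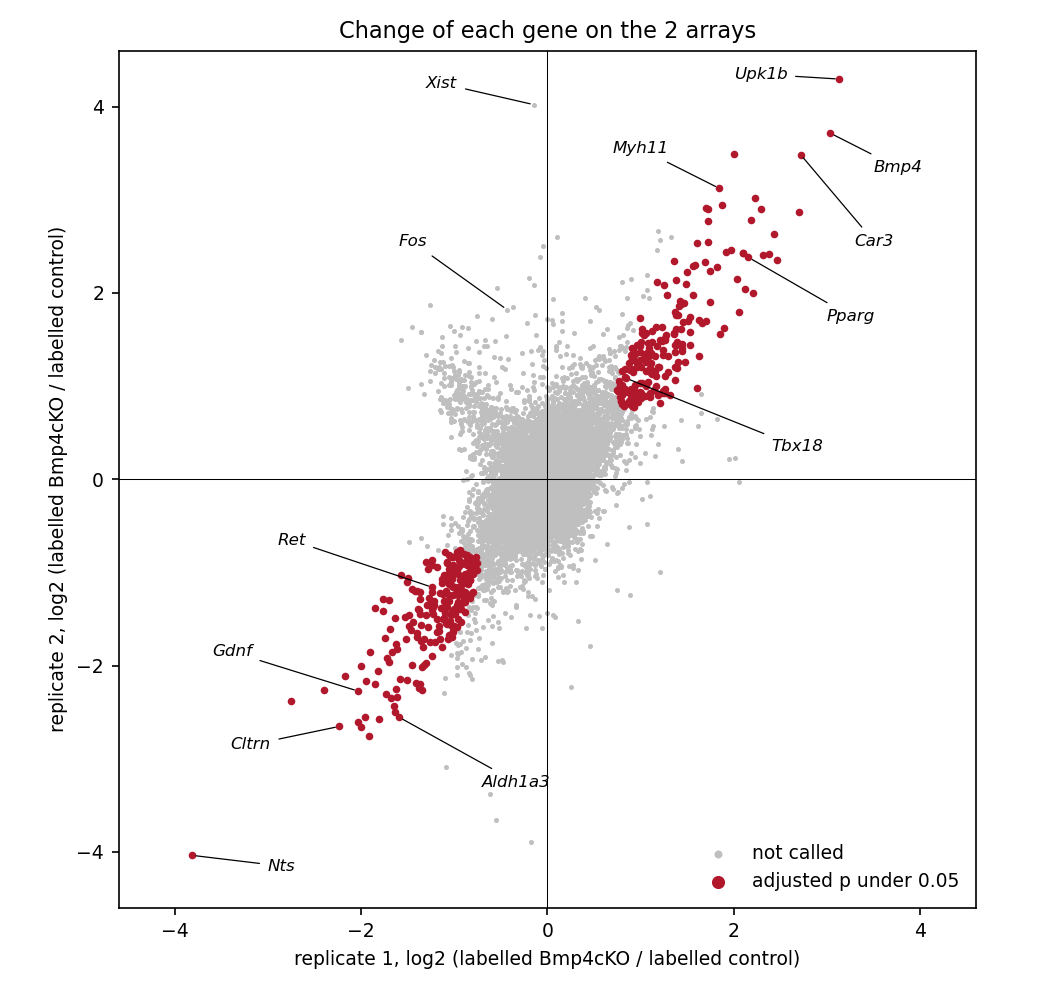
Log2 of the RNA labelled Bmp4cKO over the RNA labelled control for each of 21971 genes, replicate 1 on the x axis and replicate 2 on the y axis, with called genes in red. The 427 called genes lie in the lower left and upper right, and Fos and Xist are among genes that differ between the arrays.

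Of 17 measured genes that respond to BMP signalling 5 were higher, the direction of Bmp4, and 0 lower, or 10 and 0 adjusted over the list alone, with a median log2 of 0.59 (camera adjusted p = 8.1e-09; adjusted p = 0.66 with an estimated correlation). They included Msx2 at 1.85 ± 0.69, Smad9 at 1.18 ± 0.09 and Id4 at 1.11 ± 0.20 (SD, n = 2 arrays). Of 25 urothelial genes 8 were higher and 0 lower, or 18 and 0 adjusted over the list alone (median 0.57, camera adjusted p = 1.0e-14; adjusted p = 0.66 with an estimated correlation). Beside the uroplakins these included Pparg, a nuclear receptor gene of urothelial differentiation, at 2.27 ± 0.16. Of 16 endothelial genes none was called over all genes and 3 were higher adjusted over the list alone, and 14 were higher on both arrays (median 0.31, or 0.21 and 0.45 on the 2 arrays, camera adjusted p = 1.4e-06; adjusted p = 0.66 with an estimated correlation). Sox17 had a mean of 0.66 (0.35 and 0.96 on the 2 arrays) and Cldn5 of 0.62 (0.42 and 0.82). None of these lists passed fry, with a fry adjusted p of 0.182 for BMP target, 0.294 for urothelial and 0.425 for endothelial genes.

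Smooth muscle genes as a list did not pass the test, by a small margin. Of 21 measured, Myh11, Actg2 at 2.31 ± 0.85 and Cnn1 at 2.14 ± 0.58 were higher, and Synpo2 fell by 1.57 ± 0.33, with its 3 passing probes from -1.57 to -0.56. Adjusted over the list alone 7 were higher and 3 lower. The median was 0.06, or 0.07 and 0.25 on the 2 arrays, and the mean was 0.38. The camera adjusted p was 0.054, or 0.69 with an estimated correlation, and turned to a pass under 11 alternative settings. Of the 19 ureteric mesenchyme transcription factors, Gata6 at 1.09 ± 0.20 and Tbx18 were higher and none lower, or 5 and 1 adjusted over the list alone. The list's median was -0.02, its mean was 0.11 and the test's direction was up (camera adjusted p = 0.52).

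Of 15 measured retinoic acid pathway genes 5 were lower, the direction opposite to Bmp4, and 0 higher, or 8 and 4 adjusted over the list alone (median -0.51, camera adjusted p = 0.018; adjusted p = 0.66 with an estimated correlation). Genes of enzymes that make retinoic acid were lower, with Aldh1a3 at -2.07 ± 0.68, Aldh1a2 at -1.83 ± 0.46 and Aldh1a1 at -1.47 ± 0.48. Cyp26b1, whose product degrades retinoic acid, was also lower, at -0.87 ± 0.11. Cyp26a1 of the same list was higher on both arrays, at 1.41 and 0.33, and was not called over all genes. Of 12 SHH pathway genes none was called over all genes and 4 were lower adjusted over the list alone. The median was -0.17, or -0.32 and -0.24 on the 2 arrays (camera adjusted p = 0.0072, or 0.66 with an estimated correlation). Cdon was at -0.74, or -0.19 on a dimmer probe, and Shh at -0.71. Ptch1, Gli1 and Hhip had means of -0.11, -0.15 and 0.28. On both arrays 8 members were lower and 1 was higher. Of 18 BMP ligands and receptors, Bmp4 was higher and Bmp2 fell by 1.22 ± 0.02, with 2 higher and 6 lower adjusted over the list alone (median -0.29, or -0.11 and -0.46 on the 2 arrays, camera adjusted p = 0.033; adjusted p = 0.66 with an estimated correlation). This list did not pass with no normalization or with a minimum processed signal of 100.

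Lists of kidney, nerve, and fat and skeletal muscle cells passed the list test toward lower values in the RNA labelled Bmp4cKO, each with 1 to 3 members called lower. Of 10 kidney stroma genes, Smoc2 fell by 1.43 ± 0.40 and Alx1 by 1.30 ± 0.35, with 5 lower adjusted over the list alone (median -0.33, camera adjusted p = 0.0048). Of 12 nephron progenitor and nephron genes, Gdnf, Wt1 at -1.34 ± 0.22 and Lhx1 at -1.06 ± 0.17, or -1.68 on a dimmer probe, were lower and Crym at 1.22 ± 0.22 was higher, with 5 lower and 2 higher adjusted over the list alone (median -0.37, or -0.13 and -0.81 on the 2 arrays, camera adjusted p = 0.022). Of 12 ureteric bud tip and collecting duct genes, Wnt9b fell by 1.97 ± 0.51 and Ret was 2.29-fold lower, with 4 lower adjusted over the list alone (median -0.30, or -0.14 and -0.53 on the 2 arrays, camera adjusted p = 7.5e-04). Of 16 neuronal and Schwann cell genes 3 were lower, among them Tubb3 at -1.52 ± 0.28 and Elavl3 at -0.89 ± 0.12, with 6 lower adjusted over the list alone (median -0.14, or -0.27 and -0.10 on the 2 arrays, camera adjusted p = 0.0072). Of 11 adipocyte and skeletal muscle genes, Myog fell by 0.89 ± 0.01, with 3 lower adjusted over the list alone (median -0.16, or -0.25 and -0.07 on the 2 arrays, camera adjusted p = 0.033). With an estimated correlation the adjusted p was 0.66 for each of these 5 lists. The nephron list did not pass without the filter on dim probes, nor the adipocyte and skeletal muscle list with either of the stricter filters.

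**Figure D3:**
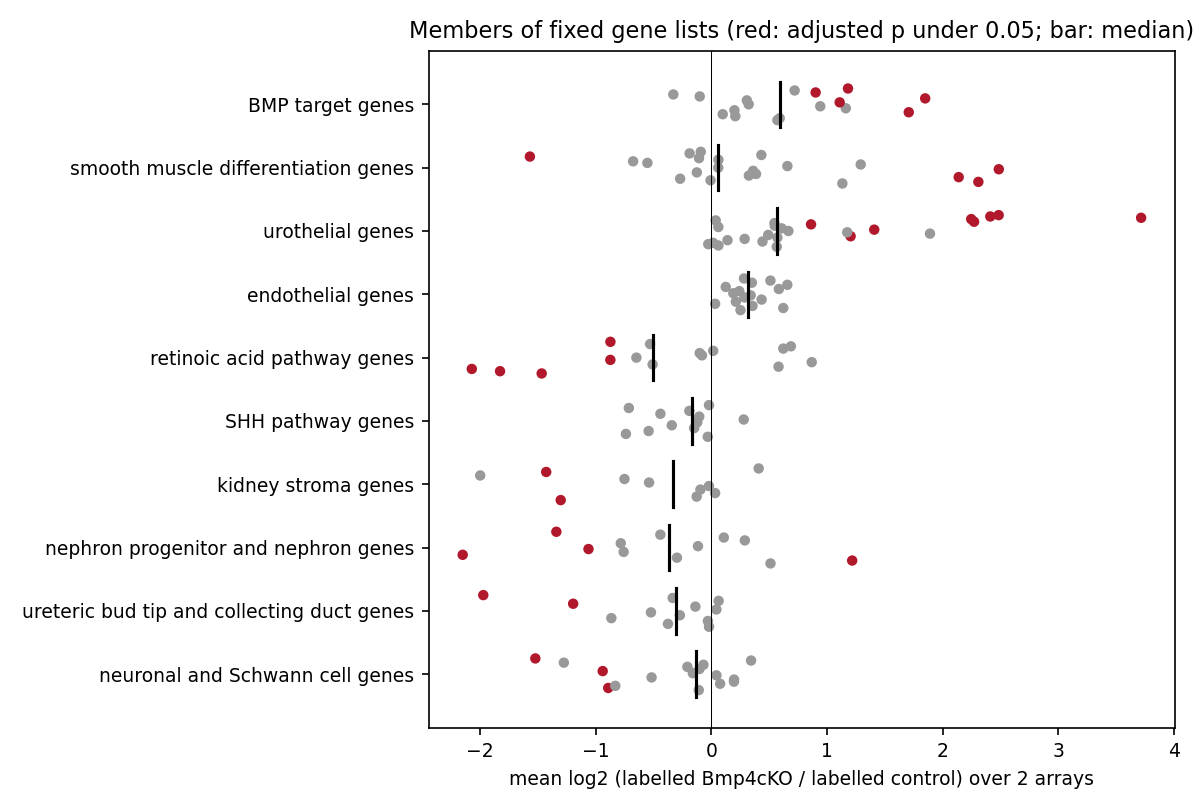
Mean log2 of the RNA labelled Bmp4cKO over the RNA labelled control on 2 arrays (x axis) for measured members of 10 fixed gene lists, 1 point per gene, red where the adjusted p was under 0.05, with a bar at each list's median. The medians run from -0.51 in the retinoic acid list to 0.59 in the BMP target list.

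The other lists did not pass camera in the reported setting, though the FGF and the immediate early and stress lists passed in 2 alternatives each and the gonad, adrenal and Wolffian duct list in 1. In the WNT pathway list Sfrp2 was higher at 1.29 ± 0.14 and Wnt9b, Apcdd1 at -0.89 ± 0.05 and Lgr5 at -0.87 ± 0.10 were lower, of 20 measured (3 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.57). In the FGF pathway list Fgfr3 at 1.68 ± 0.30 and Fgf7 at 1.67 ± 0.01 were higher, of 15 measured (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.19). Among 8 mesothelial genes Msln at 1.93 ± 0.51 and Upk3b at 1.32 ± 0.42 were higher and Wt1 was lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.89). Upk3b was well above background in the RNA labelled control on 1 array only, and ranged from 1.02 to 2.19 over the alternatives. The list's median and test were below 0, at -0.12, while its mean was 0.04. Single members were lower in 3 lists. They were Lhx1 in the gonad, adrenal and Wolffian duct list (2 higher and 4 lower of 14 adjusted over the list alone, camera adjusted p = 0.23), Ptprc at -0.80 ± 0.05 in the macrophage and leukocyte list (0 and 1 of 14, camera adjusted p = 0.81), and Cdkn1a at -1.31 ± 0.19 in the p53 and apoptosis list (1 and 2 of 13, camera adjusted p = 0.66). The call of Ptprc was borderline, at an adjusted p of 0.0499 and lost in 6 of 18 alternatives. The 3 passing probes of Cdkn1a ranged from -1.31 to -0.14, and with their mean it did not pass, at -0.55. In the last 2 of these lists the median and test were above 0, at 0.04 and 0.06, and the means below it, at -0.0014 and -0.04.

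In the 6 remaining lists no member passed over all genes. The camera adjusted p was 0.45 for the NOTCH pathway, with Jag2 at 0.68 (0.32 and 1.05 on the 2 arrays) and Lfng at 0.57. For cartilage genes it was 0.19, with Col9a3 at 0.80 and Hapln1 at 0.66 and 3 higher adjusted over the list alone. It was 0.56 for fibroblast and matrix genes, with Dpt at 0.83 and Postn at 0.71, 1 higher adjusted over the list alone, a median of -0.07, and a mean of 0.06 and a test that were above 0. It was 0.19 for erythroid genes, with Ahsp at 0.42 and Hbb-bt at 0.36, and 0.66 for cell cycle genes, with Cdk1 at 0.44 and Pcna at 0.34. For immediate early and stress genes it was 0.12, with Fos at 0.70 and Ndrg1 at 0.57. Adjusted over the list alone, 0 members passed in the NOTCH, erythroid, cell cycle and immediate early lists.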

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

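All tests weighed here were chosen after the results were seen. Y-linked signal appeared in the RNA labelled control of replicate 2, in probes that the report's gene comparison left out because they were not well above background on both arrays of a group: 2720 for Ddx3y, 2741 for Eif2s3y, 98.6 for a Uty probe and 32.4 for Kdm5d, none of them well above background in the RNA labelled Bmp4cKO of that array. The brighter of the Xist probes differed between the arrays by 4.16 on the log2 scale, at -0.14 on replicate 1 and 4.02 on replicate 2. The sex label of at least 1 RNA on replicate 2 does not match these signals.

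Other values went in opposite directions on the 2 arrays, which carry different sex labels and opposite dye orientation. For a gene, the difference between the arrays follows its mean red over green, on which 0 genes were called (limma, adjusted p under 0.05). That fit's residual holds the genotype difference, which limits it. Differences of list medians were not tested, apart from the immediate early and stress list weighed below. Replicate 2 minus replicate 1 was 2.25 for both Hbb-bt and Fos, which were higher in red than in green on both arrays, by a mean log2 of 1.13 and 1.12. For list medians it was -0.15 for ureteric mesenchyme transcription factors, 0.086 for the NOTCH pathway, 0.35 for fibroblast and matrix genes, -0.14 for macrophage and leukocyte genes, -0.26 for mesothelial genes, -0.29 for cell cycle genes and 0.74 for immediate early and stress genes.

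Bmp4 and Tbx18 were both higher in the RNA labelled Bmp4cKO. A raised non-functional Bmp4 transcript with right dye labels would go with lower BMP target genes, and their median was 0.59, with 5 called higher and 0 lower. That goes against this explanation but cannot exclude it. The rise of the list was known when the test was written, and other sources of the rise were not tested. An exchange of the dye labels on both arrays and a functional excess of Bmp4 are further explanations, and no test here tells between them. Under an excess with right labels, Bmp4 would be 10.4-fold higher in embryos whose genotype removes it where Tbx18 is active. Tbx18 would be 1.95-fold higher from 1 intact copy. The genotypes on the labels therefore argue against such an excess, without excluding it. The sign of the authors' value table does not settle the question. A table of control over Bmp4cKO with right labels would have the same sign. Read in the order of the sample titles, Bmp4cKO over control, that table puts Bmp4 and Tbx18 lower in Bmp4cKO, opposite to the dye labels. The dye labels were not changed.

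Immediate early and stress genes, switched on by a stimulus such as dissection, had a median log2 red over green of 0.39 over 18 measured members. It was 0.30 on replicate 1 and 0.44 on replicate 2, with 12 members higher in red on both arrays. The members were not alike. Junb, Dusp1 and Fos had means of 1.24, 1.15 and 1.12, while Hsp90aa1, Vegfa and Bnip3 had 0.0018, -0.08 and -0.34. Dye bias tied to signal strength would leave the list level with genes of like signal, yet the highest median among 10000 signal-matched random lists was 0.10. Such a bias was present among the 500 brightest genes, whose median was 0.54 against -0.01 for other genes. A gene-specific dye bias and more of these transcripts in the RNAs that carried the red dye, possibly from handling, were not tested, since each RNA was measured in 1 dye.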

How the results depend on the processing

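The alternatives without X and Y genes and with the sign of the authors' value table were chosen after seeing the data. Counts are given as higher and lower in the RNA labelled Bmp4cKO, against 197 and 230 called and 128 and 136 at least 2-fold. With median centring 0 and 0 were called (1761 at an unadjusted p under 0.05), and Bmp4 (3.38, adjusted p = 0.29) and Tbx18 (1.00, adjusted p = 0.36) no longer passed. With no normalization 0 and 1 were called, 32 and 85 were 2-fold, and Bmp4 was 3.36 and Tbx18 0.98, neither passing; the medians of all genes were then -0.73 and 0.70 on the 2 arrays. Dye effects left in the ratios enter the residual by the design's construction: the prior SD was 0.18 with loess, 0.23 with median centring and 1.15 with none. Over the alternatives, adjusted p ran from 4.8e-04 to 0.29 for Bmp4 and from 0.0034 to 1 for Tbx18. An intensity trend called 614 and 672, the intraspot correlation fit 384 and 440, an adjusted p under 0.10 453 and 508, and a test against 1.2-fold 90 and 83. Higher calls were 297 with offset 16 and 300 with the authors' values, whose 2-fold lower count was 214. Processed signals gave 223 and 258 2-fold genes and a 1.5-fold rule 384 and 447. The cause of these shifts was not tested. With 1 array left out, 170 to 415 higher and 233 to 339 lower genes were 2-fold on the other, Bmp4 ranged from 3.04 to 3.71 and Tbx18 from 0.85 to 1.08, with no test. With no replicate block, as 4 separate channels, 159 and 175 were called, 327 of them shared. With the sign of the authors' value table Bmp4 was -3.38 and Tbx18 -0.97. Of 25 lists, 11 passed with camera. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05), on 1 degree of freedom, where hardly any list can pass. With fry 0 passed (7 at an unadjusted p under 0.05), and other settings gave 10 to 13. Smooth muscle genes passed in 11 settings, with camera adjusted p = 0.036 without X and Y genes. Of the genes that the naming rule takes, 58 were called in the reported setting, Bmp4 and Tbx18 among them. Of the others called, all 56 lost their call with median centring and 55, all but Nts, with no normalization. Signal over background was lower in red, at 7.14 and 7.58, which limits dim probes.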

Other observations

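The joint count over both kidney lists was chosen after the result was seen. Called genes changed more on replicate 2 than on replicate 1 for 314 of 427, and the median ratio of the 2 changes was 1.16. The SD of all log2 ratios was 0.42 on replicate 2 and 0.32 on replicate 1.

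Of 22 measured members of the fixed kidney stroma and nephron lists, 5 were called lower in the RNA labelled Bmp4cKO, among them Gdnf, Wt1 and Lhx1, and 1, Crym, was called higher. On both arrays 14 were lower and 4 higher, with a median of -0.37. Some members hardly fell or did not fall. On replicates 1 and 2, Foxd1 of the stroma list was at -0.07 and -0.12. Of the nephron list, Cited1 was at 0.65 and 0.37, and Six2 at 1.21 and -0.99. Both lists lost their call with an estimated correlation (camera adjusted p = 0.66), which says little on 1 degree of freedom. These values do not decide whether the RNA labelled control held kidney tissue, and that stays open. A comparison with the members called lower was left out, because they were picked by their own fall.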
